A study of Mus musculus with 4 samples.

How the data were processed

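The series holds 2 single-cell libraries from mice whose Gm38411 locus carries an iCre and hCD2 reporter crossed to a tdTomato lineage reporter. Per the labels' protocols, tdTomato+ cells without surface B220, CD3 and Ly6C from mice aged 15 days and from adults were taken from 5 sites (bone marrow, cLN, mLN, sLN and spleen), marked with 10 hashtags, and sorted into an hCD2+ and an hCD2- pool. Each pool gave 1 RNA and 1 hashtag sample. There is 1 library per group, and the files do not link a hashtag to a tissue or age, so hashtags are given by number only.

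The authors deposited raw counts: whole-number UMI counts per feature and barcode for 32289 genes and 10 hashtags, made with Cell Ranger 9.0.1 per the file headers, on GRCm39 per the submitters' processing notes. The files keep all barcodes (2621551 and 2423179) with no cell calling. Ccl21a and Mx1, members of the fixed lists, are missing from the gene table.

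A barcode was taken as a cell when its RNA UMIs reached the larger of 1000 and 10% of the 99th percentile of the top barcodes (3852 UMIs in the hCD2+ library and 5492 in the hCD2- library), with at least 500 genes and at most 10% mitochondrial UMIs. This left 19152 and 12525 barcodes. Seurat 5.3.0 HTODemux (R 4.3.3, positive quantile 0.99) called 4144 (21.6%) and 2773 (22.1%) hashtag doublets and 15 and 46 barcodes with no hashtag, which were dropped. The doublet share may be too high, since the fold rule tried as an alternative kept 17069 and 11331 cells. The calls left 14993 and 9706 cells with 172 to 2360 and 482 to 1340 cells per hashtag. Scrublet marked 0.353% and 0.299% of these cells, against an expected rate of 8% given to it. How many doublets it missed was not tested, and doublets within a hashtag are taken to remain. Cells had a median of 11282 and 12710 UMIs and 3614 and 3681.5 genes, and held 186665119 and 142695570 UMIs.

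Cells of both libraries were clustered together in scanpy 1.11.5 without integration: 10000 counts per cell, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), with the reporter and its locus left out of the clustering genes. This gave 34 clusters. A cluster was named X-like after the marker list with the highest score when at least 3 of its markers were raised 2-fold over the 25th percentile of clusters, at least 50% of its cells carried 3 of them, no other lineage list had more markers among the top 10 genes, and the next lineage list was over 0.25 behind in mean log2 or had at least 2 fewer markers in the top 10. The lists for stages, mature DC and ILC progenitor, were left out of these comparisons. The mature DC list named a cluster only where it outscored a lineage list with fewer than 50% of its markers raised. Clusters 16 and 30 were therefore named RORgt DC-like at scores of 3.50 and 2.33 although the mature DC list scored 4.34 and 3.90. The details of this rule were set on the data, and the baseline of the 25th percentile was chosen after a comparison with all other cells had left the most common class without a name. Clusters 10, 22 and 23 stayed unnamed, at 4.38% and 2.42%, 1.77% and 0.175%, and 0.981% and 1.33% of the hCD2+ and hCD2- libraries.

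With 1 library per group no test was made, and the planned count of genes past a fold is not given since it would have no error. UMIs were summed per gene over the cells of a library, class or cluster, scaled to CPM (UMIs per 1000000 UMIs of the same cells), and compared as log2 ratios of the hCD2+ over the hCD2- library with a pseudocount of 10 CPM. Shares carry exact Clopper-Pearson intervals and ratios exact Poisson intervals at 95%, for counting error only. Genes with CPM of at least 20 in 1 library and at least 100 UMIs in both together were measured. Classes with at least 100 cells in each library were compared. The rule for named genes took the 12 genes with the largest log2 ratio each way that kept their direction in at least 80% of the hashtags with at least 50 cells in each library, leaving out mitochondrial, ribosomal, model, sex-linked and receptor variable genes, plus up to 4 members of each fixed list. The median of each of the fixed gene lists was set against 10000 random lists matched on mean expression in 20 bins, which describes these libraries and not the conditions. Detection was also computed after thinning cells to 3852 UMIs. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9.

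The measures were tested on simulated Poisson counts drawn at the depth of these libraries. Intervals of ratios held the true value in 94.9% of unchanged genes over all cells, in 95.1% in ILC3-like cells and in 95.5% in cluster 8. For genes changed 2-fold they held it in 90.0%, 91.0% and 98.0% of 100 genes. The direction was right in 100% of genes changed 2-fold or 4-fold. Such counts hold no spread between cells, hashtags or mice, so the intervals were not tested against that spread. The gene lists, markers, thresholds, named-gene rule and most alternatives were set before the data were examined. Alternatives covered the UMI floor, the mitochondrial limit, the hashtag rule, Scrublet calls, clustering resolution, normalization, pseudocount, the CPM floor, thinned cells, hashtags weighted equally or left out in turn, and variable genes. A floor of 2000 UMIs, a common threshold in both libraries and a RORgt DC-like class without cluster 16 were added after the data were seen. Hashtag or tissue comparisons were left out because the files do not name the tissues, and surface B220 was left out because 3' counts do not tell its isoform. Results of some genes are not reported here and were left out of the table of alternatives.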

Results

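ILC3-like cells made up 61.8% of the 14993 cells in the library sorted as hCD2+ (95% interval 61.0 to 62.6) and 37.0% of the 9706 cells in the library sorted as hCD2- (36.1 to 38.0). Their share was higher in the hCD2+ library in 9 of 10 hashtags, hashtag 9 being the exception with 21.7% against 26.3%. RORgt DC-like cells held 10.4% (9.87 to 10.9) and 10.9% (10.3 to 11.6), and were higher in the hCD2+ library in 5 hashtags and lower in 5. Cluster 16 had none of the class's markers among its top 10 genes over the 25th percentile of clusters. Without it, RORgt DC-like cells held 9.16% (8.70 to 9.63) and 7.24% (6.74 to 7.78), with 5 of 10 hashtags higher in the hCD2+ library. The hashtags split evenly with and without cluster 16, and there was 1 library per group, so neither order of the libraries is firm. The counting intervals overlapped for the whole class but not without cluster 16. Alpha-beta T-like cells made up 19.6% and 10.8%, though without hashtag 9 the hCD2+ value was 10.5% and 6 of 10 hashtags were higher in that library. B-like cells were nearly confined to the hCD2- library, 25.1% against 0.740%, and lower in the hCD2+ library in 10 of 10 hashtags. Neutrophil-like cells (7.36% against 0.180%), monocyte or macrophage-like cells (202 cells, 2.08%, against 15 cells) and NK or ILC1-like cells (2.03% against 0.0267%) were also mostly found in the hCD2- library. NK or ILC1-like cells were lower in the hCD2+ library in 10 of 10 hashtags, and the others in 8 of 10. Hashtags 1 and 8 held 217 and 486 of its 714 neutrophil-like cells and 54 and 128 of its 202 monocyte or macrophage-like cells, and hashtag 8 held 94 of its 197 NK or ILC1-like cells. Mature DC-like cells numbered 52 in the hCD2- library and 1 in the hCD2+ library, and pDC-like cells 29 and 1. Cells in clusters with no name made up 7.12% and 3.93%. All of these shares lie downstream of a sort that took tdTomato+ cells lacking surface B220, CD3 and Ly6C and divided them by hCD2, and of cell thresholds of 3852 UMIs in the hCD2+ library and 5492 UMIs in the hCD2- library. The intervals cover counting error only, with 1 library per group.

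**Figure D1:**
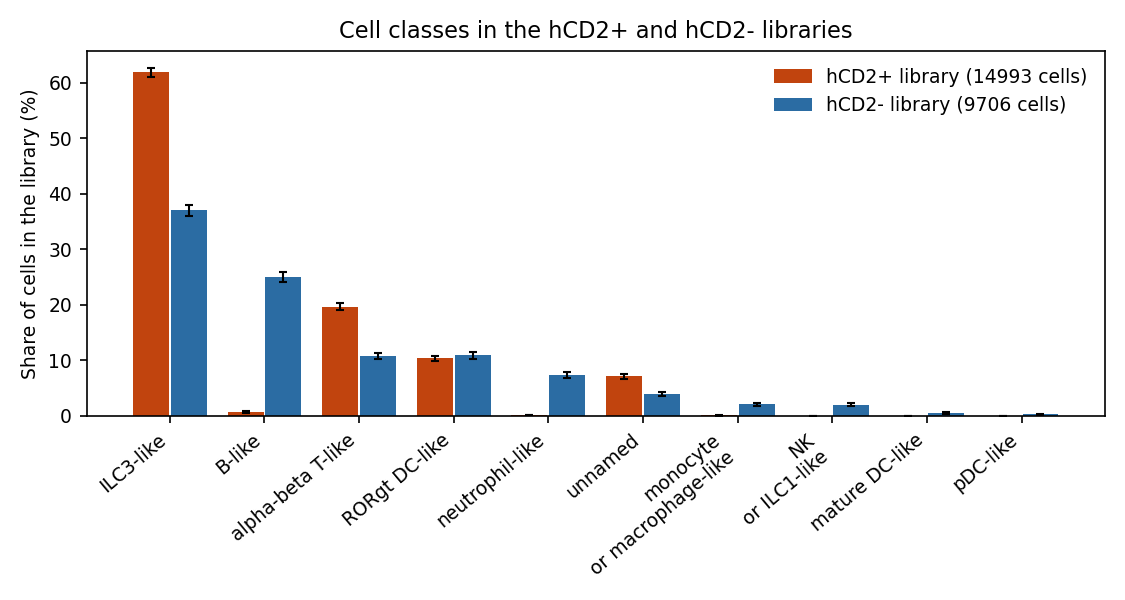
Shares of cell classes in each library with 95% counting intervals, led by ILC3-like cells at 61.8% in the hCD2+ library and 37.0% in the hCD2- library.

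The hCD2 reporter transcript stood at 67.3 CPM in the hCD2+ library and 28.4 CPM in the hCD2- library, a ratio of 2.37 (2.29 to 2.45). Gm38411, the locus that carries the reporter, gave 74.4 and 28.9 CPM (ratio 2.57, 2.48 to 2.66). hCD2 and Gm38411 were higher in the hCD2+ library in 10 of 10 hashtags. iCre gave 1063 and 199 UMIs, and tdTomato, on which both libraries were sorted, gave 684 and 517 CPM. In ILC3-like cells the gap in hCD2 was smaller than over all cells, 62.6 against 53.4 CPM (ratio 1.17, 1.12 to 1.23). It had that direction in 6 of the 8 hashtags with at least 50 such cells in each library. In alpha-beta T-like cells hCD2 was at 54.1 and 18.5 CPM (ratio 2.93, 2.56 to 3.36), in that direction in 6 of 6 such hashtags. hCD2 was detected in 42.1% and 41.2% of ILC3-like cells (median depths 11175 and 13445 UMIs) and in 39.3% and 16.2% of alpha-beta T-like cells. It was detected in 65.2% and 41.6% of RORgt DC-like cells and in 84.1% and 78.8% of cells of cluster 8 within that class (25316.5 and 29173 UMIs). Within clusters 13 and 16 of the class it was detected in 28.15% and 27.99%, and in 40.78% and 41.29%. Cluster 8 held 63.1% and 18.2% of the class, so the gap over the class also carries the mix of clusters. In B-like cells, a class that should lack hCD2, it was detected in 2.70% and 0.494% (6812 and 8045 UMIs). With every cell thinned to 3852 UMIs these shares were 19.5% and 16.8% of ILC3-like cells and 17.5% and 5.74% of alpha-beta T-like cells. RORgt DC-like cells were then at 23.7% and 12.1%. Clusters 8, 13 and 16 were at 31.5% and 23.3%, 7.04% and 7.90%, and 8.38% and 10.1%. B-like cells were at 0% (up to 3.27%) and 0.206%. Of the genes tied to the gate, Cd79a (8.51 against 287 CPM) and Ly6c2 (2.75 against 175 CPM) were far lower in the hCD2+ library, each in 10 of 10 hashtags, while Cd3e was higher (104 against 51.4 CPM), though in 6 of 10 hashtags only. A cell sorted as hCD2- can carry the hCD2 transcript, and detection fell with depth, so detection does not give the share of cells with the protein.

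**Figure D2:**
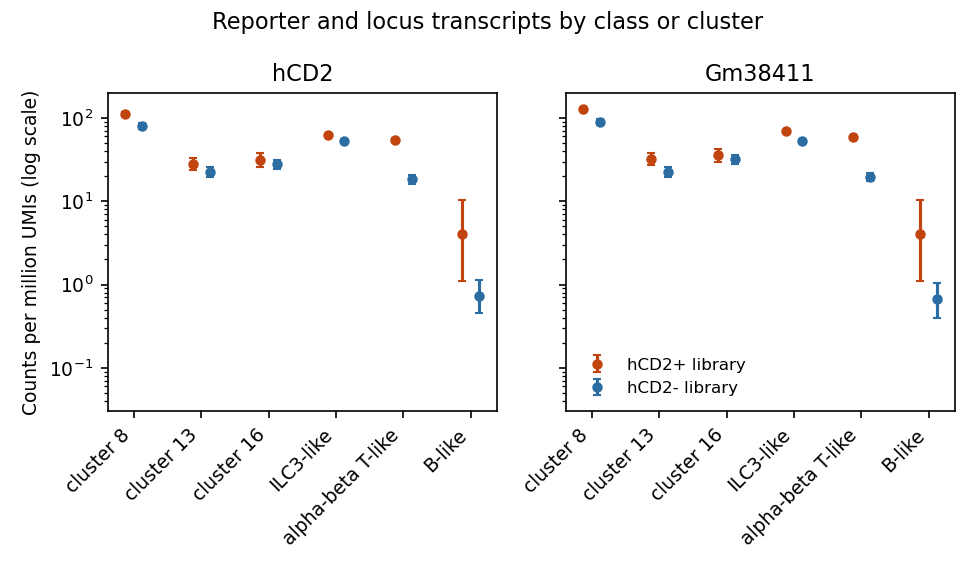
hCD2 and Gm38411 by class or cluster, with 95% counting intervals; hCD2 was at 113 CPM and 79.9 CPM in cluster 8 and at 62.6 and 53.4 CPM in ILC3-like cells.

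Over all cells, the genes with the largest ratios toward the hCD2+ library included Cd40lg, a costimulatory ligand of activated T cells (77.0 against 15.6 CPM, log2 ratio 1.76), Icos (330 against 111 CPM, 1.49), Bcl11b, a T-lineage transcription factor (118 against 39.2 CPM, 1.38), Thy1 (169 against 65.6 CPM, 1.24), and Tcrg-C1 (116 against 45.3 CPM, 1.19). Others were Clec10a, a C-type lectin (29.4 against 4.02 CPM, 1.49), Dlg2 (40.1 against 6.01 CPM, 1.64), Ramp3 (1.41), Stab2 (1.32), Upp1 (1.28), Itgae (1.28) and Jaml (1.24). The genes furthest toward the hCD2- library were those of neutrophil granules and antimicrobial proteins, S100a9 (129 against 8124 CPM, log2 ratio -5.87), S100a8 (-5.77), Ngp (-5.73), Camp (-5.48), Ltf (-5.27), Lcn2 (-5.22), Chil3 (-4.76), Retnlg (-4.65) and Wfdc21 (-4.31), with Lyz2 (-4.89) and the immunoglobulin genes Igkc (-4.96) and Jchain (-4.50). Leaving out 1 hashtag moved 9 of the 24 genes the rule named over all cells by more than 1.5-fold. Without hashtag 12, Jchain was at -1.93 and Igkc at -3.71. Without hashtag 8, Chil3 was at -3.42, Wfdc21 at -3.07, Ltf at -4.46 and Retnlg at -3.96, while S100a9 was at -6.66, S100a8 at -6.52 and Camp at -6.17. Among the lists, innate lymphoid transcription factors had a median log2 ratio of 0.78 (percentile 100 among random lists matched on expression), with Zbtb16 at 1.14 and Maf at 1.00. Type 3 cytokines and their receptors stood at 0.68 (percentile 99.9, Il22 0.68 and Il23r 0.84) and the lymphotoxin and TNF family at 0.67 (percentile 100, Tnf 1.07 and Ltb 0.67). Proliferation genes stood at -1.26 (percentile 0, Mki67 -1.87 and Top2a -1.57), although Mki67 had that direction in only 5 of 10 hashtags. These values combine differences in cell make-up with differences within classes, and the share of neutrophil-like and B-like cells differed between the libraries by the values above.

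Within the RORgt DC-like class the libraries differed in which clusters they held. Cluster 8 made up 63.1% of the class in the hCD2+ library and 18.2% in the hCD2- library, cluster 13 made up 17.4% and 41.8%, and cluster 16 made up 11.5% and 33.6%. Clusters 29 (5.03% and 1.98%) and 30 (2.90% and 4.34%) held the rest. Among the 8 hashtags with at least 20 cells of the class in each library, a minimum set after the data were seen, cluster 8 was higher in the hCD2+ library in 8 of 8, by 30.7 to 52.4 percentage points, and clusters 13 and 16 were lower in 8 of 8. Shares of a class move against each other. As a share of all cells, cluster 8 was higher in the hCD2+ library in 9 of 10 hashtags. Cluster 13 was lower in 7 and higher in 3, and cluster 16 was lower in 6 and higher in 2. The clusters were separated on their own genes, so the levels that follow describe them and test nothing: Aire, a regulator of tissue antigen expression, was at 17.3, 143 and 591 CPM in clusters 8, 13 and 16, and Ccr7, the receptor that guides dendritic cells to lymph nodes, at 330, 313 and 2450 CPM. Prdm16 was at 1381 CPM in cluster 8. Cluster 16 had none of the class's markers and 1 mature DC marker, Ccr7, among its top 10 genes over the naming baseline. Yet 9 of the 12 class markers were raised in it, at a score of 3.50. Cluster 8 had 6 of 12 raised at 2.93, and cluster 13 had 9 of 12 at 3.185. The mature DC list outscored the class list in cluster 16 (4.34) but not in clusters 8 (2.20) and 13 (2.95). The class total therefore depends on how clusters 8 and 16 are named, and expression was compared between libraries by cluster.

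**Figure D3:**
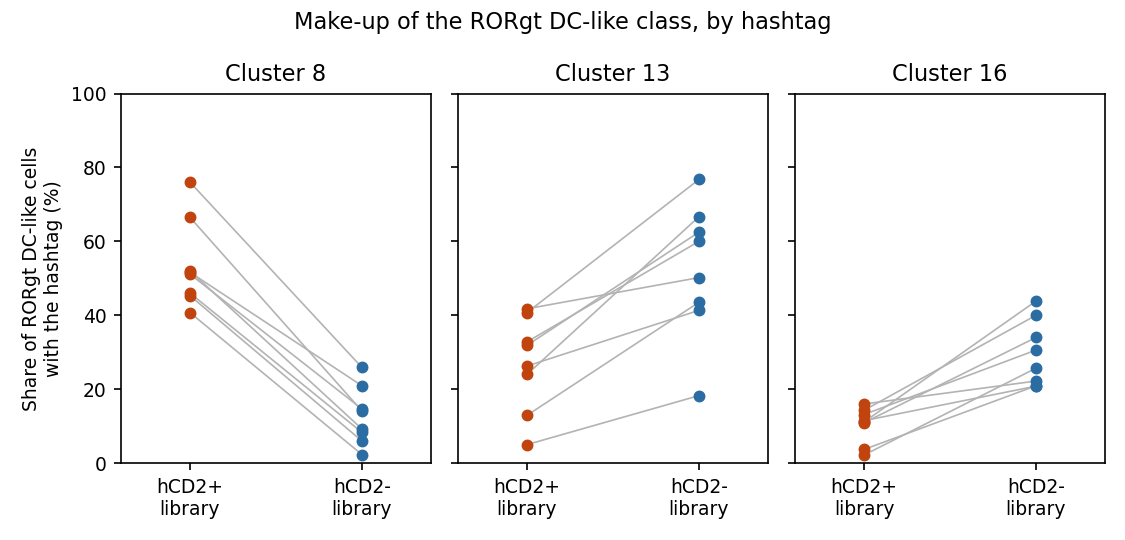
Share of RORgt DC-like cells held by clusters 8, 13 and 16 in each of 8 hashtags; over all hashtags cluster 8 held 63.1% in the hCD2+ library and 18.2% in the hCD2- library.

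In cluster 8 (980 and 193 cells) hCD2 was at 113 and 79.9 CPM (ratio 1.41, 1.28 to 1.56) and Gm38411 was at 127 and 88.8 CPM (1.44, 1.31 to 1.58). Genes toward the hCD2+ library were Clec10a (156 against 29.1 CPM, log2 ratio 2.09) and Mgl2 (1.61), 2 C-type lectins, Itgax, the integrin chain CD11c (146 against 47.3 CPM, 1.44), the cytokine Il1b (1.73), Plac8 (1.68), Clnk (1.58), Hmox1 (1.55), Gpr39 (1.39) and the stress or immediate early genes Hspa1a (1.70), Hspa1b (1.53), Egr3 (1.38) and Atf3 (1.34). Toward the hCD2- library stood Aire (10.8 against 45.5 CPM, -1.42), Tnni1 (-1.88), Gal (-1.35), Slc28a2 (-1.19), the B-lineage genes Bank1 (-1.75) and Ebf1 (-1.73), and the cell cycle genes Pclaf (-1.43), Hist1h1b (-1.36) and Ccnd1 (-1.26). Leaving out 1 hashtag moved 8 of the 24 named genes by more than 1.5-fold. Il1b ranged from 0.86 to 2.40, Plac8 from 1.07 to 2.14, Clnk from 1.005 to 2.34, and Hspa1b from 1.07 to 2.15. Egr3 ranged from 1.03 to 2.15, Atf3 from 1.055 to 2.31, Bank1 from -2.39 to -1.71 and Ebf1 from -2.085 to -0.93. The neutrophil genes S100a9 (1.28 against 74.8 CPM), S100a8 (-2.84) and Camp (-1.61) were also toward the hCD2- library. S100a9 was at a like level in alpha-beta T-like cells of that library (70.9 CPM) and at 4039 CPM in its empty droplets, so these counts are not taken as expression by cluster 8. Whether the counts of Bank1 and Ebf1 are expression by cluster 8 was not settled. Cd79a, another B-lineage gene, moved the same way in cluster 8 (1.16 and 4.53 CPM) and in the empty droplets (6.69 and 177 CPM). Yet Bank1 and Ebf1, as named genes, reached at least 20 CPM in cluster 8 of the hCD2- library, above Cd79a. Bank1 was less abundant than Cd79a in B-like cells of that library, so the Cd79a level does not account for Bank1. The rule that a named gene keep its direction over hashtags rested on 1 hashtag in clusters 8, 13 and 16. Aire and Tnni1 were among the top 10 genes of cluster 16 against the rest, and Gal among those of cluster 13. Both clusters held more of the class in the hCD2- library. Clec10a and Itgax were among those of the unnamed cluster 22, with 265 and 17 cells. Differences within clusters 8, 13 and 16 were not separated from the mix of nearby clusters.

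All 12 measured dissociation and immediate early genes were higher in the hCD2+ library in cluster 8 (median 0.85, percentile 100), 4 of them at least 2-fold (Hspa1a, Hspa1b, Atf3 and Egr1, the last at 1.27). Fos was at 0.74 and Junb at 0.72. Proliferation genes were lower (median -0.77, percentile 0), with Top2a at -1.10, Stmn1 at -1.04 and Mki67 at -0.47 (the other way in the 1 hashtag used). Neuronal and adhesion genes were also lower (-0.65, percentile 0), with Kif21a at -1.05 against Epcam at 0.35. Chemokines (0.63, percentile 100), lymphotoxin and TNF family genes (0.41), Notch signalling genes (0.37), interferon response genes (0.37), DC growth factor receptors and pan-DC genes (0.34) and retinoid and nuclear receptors (0.26) lay above the median of random lists. Lymphoid antigen receptor and recombination genes (-0.42) and costimulation genes (-0.34, Icosl -0.78) lay below it. Smaller values were found for MHC class II presentation (0.08), DC transcription factors (0.12, Irf8 0.56), chemokine receptors (0.21), type 3 cytokines and receptors (-0.07), tolerance and coinhibitory genes (-0.15) and innate lymphoid transcription factors (-0.17). In cluster 13 (270 and 443 cells) Tnfsf11, which encodes RANKL, was at 159 and 41.1 CPM (1.73), Clnk at 1.41 and Kmo at 1.23, against Ccl22 at -1.41 and Ctnna3 at -1.41. Immediate early genes had a median of 0.53 there, and neuronal and adhesion genes -0.39. In cluster 16 (179 and 356 cells) the stress genes Hspa1a (1.46) and Hspa1b (1.31) and the chemokines Cxcl9 (1.29) and Cxcl10 (1.14) were toward the hCD2+ library. The median of the chemokine list was 1.14, and Ccl22 had 1.76 but went the other way in the 1 hashtag used. Csmd1 (-1.67), Nrg1 (-1.35) and Ctnna3 (-1.20) were toward the hCD2- library, Csmd1 ranging from -2.61 to -1.28 with 1 hashtag left out.

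In ILC3-like cells (9270 and 3595 cells) the genes of MHC class II presentation were lower in the hCD2+ library, with a median log2 ratio of -0.75 (percentile 0) and 9 of 10 members below 0. Cd74, the invariant chain, was at 1887 and 3664 CPM (log2 ratio -0.95), H2-Ab1 at 401 and 768 CPM (-0.92), H2-Eb1 at -0.90, H2-Aa at -0.85, H2-DMb2 at -0.84 and Ciita, the master regulator of these genes, at -0.62, each lower in 8 of 8 hashtags. Ctss was the exception at 0.03. Dpp10 (-0.99) and Camk1d (-0.83) were also lower. Genes toward the hCD2+ library were Ikzf3 (83.1 against 39.5 CPM, 0.91), Ncr1, which encodes the receptor NKp46 (45.2 against 20.7 CPM, 0.85), Tbx21, which encodes T-bet (21.7 against 10.7 CPM, 0.61), Klrk1 (0.50), Upp1 (0.73), Tcrg-C4 (0.60), Thy1 (0.58), Ucp2 (0.54), Gimap4 (0.54), Smco4 (0.52), Skap1 (0.48) and Anxa2 (0.45). Ncr1, Tbx21 and Klrk1 were among the top 10 genes of cluster 12 against the rest. That cluster held 649 of the ILC3-like cells in the hCD2+ library and 112 in the hCD2- library, and the mix of clusters was not held fixed for these genes. Type 3 cytokines and receptors had a median of -0.06, with Il22 at 2473 and 2568 CPM, and immediate early genes one of -0.03. S100a9 (1.31 against 71.0 CPM), S100a8 (-2.75), Camp (-1.85), Ngp (-1.84) and Igkc (-1.65), genes of neutrophils and B cells, were lower in the hCD2+ library in these cells, and S100a9 was at 32.7 and 4039 CPM in the empty droplets of the libraries.

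**Figure D4:**
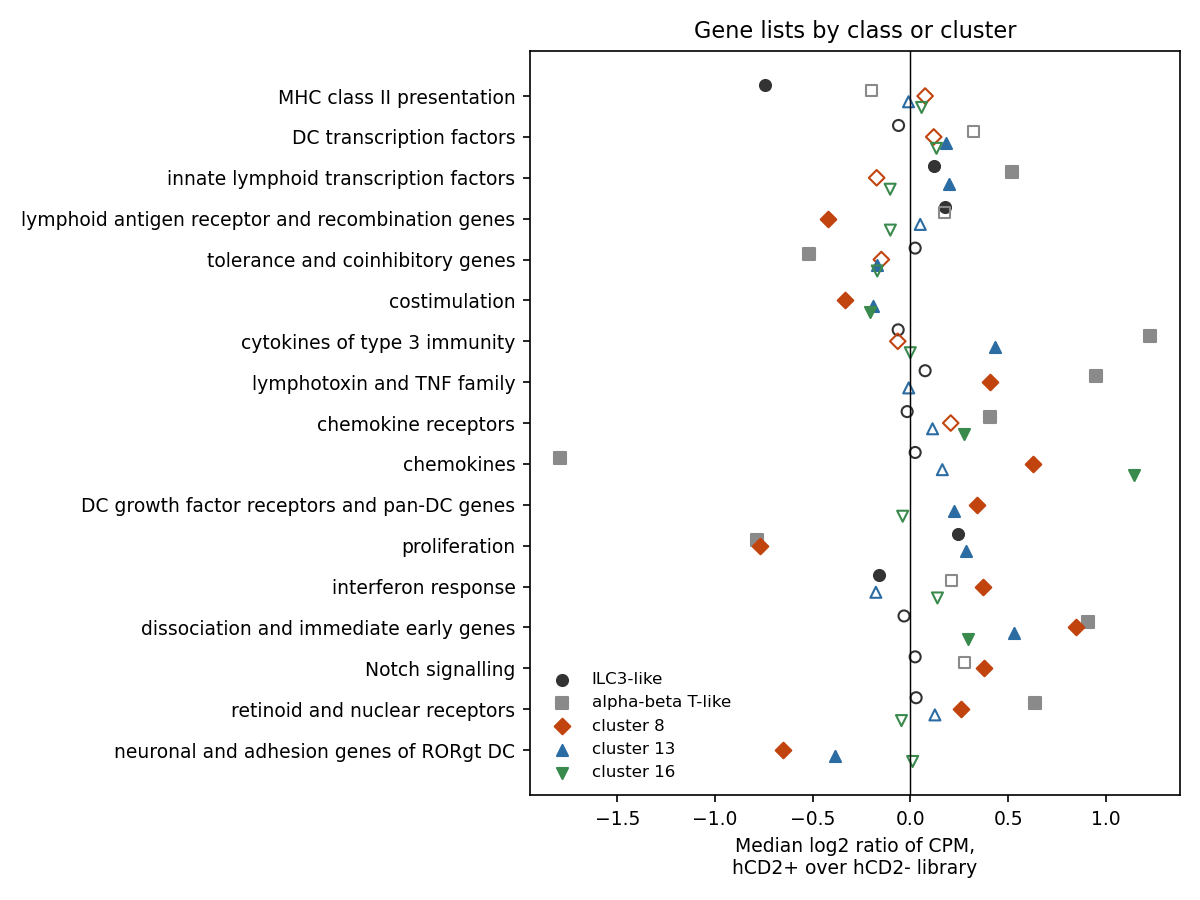
Median log2 ratio of each gene list by class or cluster, filled where the list lay outside the middle 95% of random lists; MHC class II presentation was at -0.75 in ILC3-like cells and immediate early genes at 0.85 in cluster 8.

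Alpha-beta T-like cells of the libraries came from different clusters. Cluster 1 held 2377 of the 2944 cells in the hCD2+ library, and cluster 15, which also carried NK cell genes, held 564 of the 1046 cells in the hCD2- library and 6 in the hCD2+ library. Genes of type 3 immunity were toward the hCD2+ library (median 1.23, percentile 100), with Il22 at 208 and 57.8 CPM (1.68), Il1r1 at 1.36 and Il23r at 1.29. Also toward it were Dntt, which adds nucleotides during receptor rearrangement (2083 against 51 UMIs, 2.49), Arpp21 (2.77), Ccr9 (1.57), Pxdc1 (1.47), Abi3bp (1.44), Cd40lg (1.43), Sdc1 (1.41), Tmem176a (449.5 against 164 CPM), Cysltr1 (1.37) and Adam12 (1.36). Dntt, Arpp21 and Ccr9 were among the top genes of cluster 25, which held 246 cells of the class in the hCD2+ library and 9 in the hCD2- library. Without hashtag 8 they were at 1.16, 1.52 and 0.49, and without hashtag 9 at 3.49, 3.72 and 2.45. In all, leaving out 1 hashtag moved 13 of the 23 named genes by more than 1.5-fold. They were the 12 named toward the hCD2+ library, each of which rose without hashtag 9 (Il22 to 2.32, Il1r1 to 2.21 and Abi3bp to 2.39), and Klre1. Genes of cytotoxic and NK cells were toward the hCD2- library: Ccl5 (9.31 against 1872 CPM, -6.61), Klrd1 (-4.88), Klra1 (-4.87), Klra7 (-4.81), Klre1 (-4.01), Klrc1 (-3.52) and Xcl1 (-3.98), with Ly6c2 (-5.50), Ms4a4b (-4.38), Samd3 (-3.98) and Gimap4 (-3.92). In B-like cells, with 111 cells in the hCD2+ library and no hashtag with enough cells in both, no genes were named, and Cd79a was at 1442 and 1487 CPM.

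RORgt DC-like cells were set against the other classes within each library. The class was taken whole, with cluster 16 at 11.5% and 33.6% of it. Compared with ILC3-like cells they had more of the MHC class II presentation genes (median log2 ratio 2.46 in the hCD2+ library and 1.46 in the hCD2- library), with 10 of 10 members at least 2-fold higher in both, of costimulation genes (1.88 and 2.64) and of DC growth factor receptors and pan-DC genes (2.84 and 2.49). Innate lymphoid transcription factors were lower, -1.69 and -1.54 (percentile 0 in both). Compared with alpha-beta T-like cells the MHC class II medians were 4.55 and 4.78, and DC transcription factors stood at 1.92 and 2.51, against 0.16 and 0.20 when compared with ILC3-like cells. Compared with B-like cells the MHC class II medians were only 0.42 and 0.78, with 0 and 3 of 10 members at least 2-fold higher. Without cluster 16 the MHC class II medians against ILC3-like cells were 2.42 and 1.43, those of costimulation genes 1.76 and 2.37, those of DC growth factor receptors and pan-DC genes 2.77 and 1.775, and those of innate lymphoid transcription factors -1.71 and -1.37. The profile of RORgt DC-like cells correlated with that of ILC3-like cells at Spearman 0.699 in the hCD2+ library and 0.711 in the hCD2- library, and with that of alpha-beta T-like cells at 0.630 and 0.625, and with that of B-like cells at 0.646 and 0.618. ILC3-like and alpha-beta T-like cells correlated with each other at 0.876 and 0.858. In the hCD2- library the correlation of RORgt DC-like cells with monocyte or macrophage-like cells was 0.587. Over variable genes alone the correlations of RORgt DC-like cells were far lower, 0.369 and 0.436 with ILC3-like cells, 0.212 and 0.208 with alpha-beta T-like cells, 0.226 and 0.247 with B-like cells and 0.208 with monocyte or macrophage-like cells. List members on the RORgt DC, ILC3, alpha-beta T or B marker lists were left out here. Members on other marker lists, such as Relb of the mature DC list, stayed in. Genes are no replicates, and the 52 mature DC-like cells and 29 pDC-like cells were too few for a comparison with other dendritic cells.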

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

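The floor of 2000 UMIs, the common UMI threshold in both libraries and the RORgt DC-like class without cluster 16 were chosen after the data were seen. ILC3-like cells kept the higher share in the hCD2+ library under every setting tried. With a floor of 500 UMIs that share was 48.2%, and RORgt DC-like cells were at 9.31% and 9.90% (hCD2+ and hCD2- library). With 2000 UMIs in both, ILC3-like cells were at 69.3% and 45.4% and RORgt DC-like cells at 8.64% and 8.26%, the order of the libraries turning for the latter. RORgt DC-like cells were at 9.52% and 9.84% with a mitochondrial limit of 5%. ILC3-like cells were at 62.9% and 38.6% with a limit of 20%, 64.3% and 38.3% under the hashtag fold rule (where alpha-beta T-like cells of the hCD2- library fell from 10.8% to 5.13%), 58.0% and 35.9% with cells without a hashtag kept, and 65.9% and 39.2% at Leiden 0.5. At Leiden 2.0 they were at 56.1% and 35.2%, RORgt DC-like cells at 7.34% and 9.83%, and their log2 ratio of hCD2 at 0.93. Without cluster 16 RORgt DC-like cells were at 9.16% and 7.24%, and correlated at 0.709 and 0.740 with ILC3-like and 0.641 and 0.655 with alpha-beta T-like cells. Hashtag calls were remade under each cell filter, which is why a stricter mitochondrial limit gave more hCD2+ cells (15273). With a pseudocount of 1 CPM, hCD2 was at 1.22 over all cells and at 1.225 in RORgt DC-like cells. Over variable genes alone, correlations of RORgt DC-like cells fell to 0.369 and 0.436 with ILC3-like and 0.212 and 0.208 with alpha-beta T-like cells.

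Leaving out each hashtag in turn gave 7.66% to 12.1% and 8.71% to 12.5% for RORgt DC-like cells, 58.6% to 69.3% and 32.2% to 42.3% for ILC3-like cells, and log2 ratios over all cells of 0.82 to 1.08 for hCD2. The median of lymphoid antigen receptor and recombination genes over all cells turned from -0.44 to 0.60 with a CPM floor of 100, 0.25 with thinned cells and 0.64 with hashtags weighted equally. That of the lymphotoxin and TNF family in RORgt DC-like cells turned from 0.78 to -0.036 at Leiden 2.0, and that of interferon response there from -0.44 to 0.27 without cluster 16. Except where the settings' construction shows it (fewer genes, other cells), the cause was not tested. Each of 2535 values of the 167 named gene results kept its direction. These genes were picked for large ratios with a kept direction, and the settings reuse the same cells. The count was thus nearly fixed by the choice and gives no support of its own. Of all values outside the main results, named genes included, 753 moved past their interval or tolerance and 2597 did not. Of the values of the main results, 69 moved and 107 did not. These counts include settings that could move little, such as dropped Scrublet calls (3 of 272 values moved). Over all cells, 31 of 43 values moved with hashtags weighted equally and 27 of 42 with thinned cells. With a pseudocount of 1 CPM, 148 of 294 values moved. The CPM floor was varied over all cells only, where hCD2 and Gm38411 lie below 100 CPM and have no value with that floor. The planned floor of 2000 UMIs or the rule equals the main setting, and a pseudocount cannot move a rank correlation. Median-of-ratios factors moved the median of all genes by at most 0.09. Depth limits small groups most: in the hCD2+ library B-like cells had 981814 UMIs, where 3 UMIs are 3.06 CPM, and cluster 16 had 3613909 UMIs (0.830 CPM). With 1 library per group, differences between mice or sorts could not be measured.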

Other observations

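The tests of hashtag mix for the make-up of the RORgt DC-like class and for MHC class II genes, of doublets with cells rich in MHC class II, of the hCD2 transcript level of the clusters and of handling across the whole library were chosen only after the result was seen, as was the upper bound given for free RNA.

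Cluster 22, left without a name because the cDC2 and ILC3 marker lists scored close together, held 265 cells in the hCD2+ library and 17 in the hCD2- library, with 224 of the 265 in hashtag 8, where it made up 32.5% of cells, and 24 in hashtag 1. It carried hCD2 (125 CPM) and Gm38411 (129 CPM) together with Tox (1302 CPM), a transcription factor of early innate lymphoid cells, Flt3 (157 CPM), the receptor for a dendritic cell growth factor, Il7r (636 CPM), Prdm16 (480 CPM), Clec10a (330 CPM) and H2-Aa (4594 CPM). Cluster 8 had 16.9 CPM of Tox, 39.2 CPM of Flt3, 65.1 CPM of Il7r, 133 CPM of Clec10a and 1381 CPM of Prdm16. In the hCD2+ library the profile of cluster 22 correlated with that of cluster 8 at 0.821 and with that of ILC3-like cells at 0.776. Its values with clusters 13 and 16 were 0.778 and 0.642, and with B-like and alpha-beta T-like cells 0.734 and 0.728. Over variable genes alone it correlated at 0.689 with cluster 8 and 0.559 with ILC3-like cells. With clusters 13 and 16 it was then at 0.548 and 0.401, and with B-like and alpha-beta T-like cells at 0.414 and 0.439. tdTomato stood at 203 CPM in cluster 22 against 532 CPM in cluster 8. These genes were named after their values were seen.

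Cluster 25, within the alpha-beta T-like class, held 246 and 9 cells and carried the recombination genes Rag1 (900 CPM) and Dntt (1342 CPM) with Cd8b1 (397 CPM) and Cd4 (674 CPM), at a median of 5811 UMIs. Cluster 10 (656 and 235 cells) carried Cd4 (716 CPM) and Il22 (151 CPM) with little Cd3e (2.20 CPM). Cluster 23 (147 and 129 cells) was led by haemoglobin and histone genes, with Mki67 at 1276 CPM and a median of 29167 UMIs. Only 10.1% of its cells carried at least 3 erythroid markers. tdTomato was detected in 49.5% of B-like cells in the hCD2+ library and 85.3% in the hCD2- library, and in 38.7% and 68.1% after thinning.

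The make-up of the RORgt DC-like class differed by 44.9 percentage points for cluster 8. With the threshold of 5492 UMIs in both libraries the difference was 46.9 points, and as a mean over 8 hashtags it was 41.0 points, so neither the thresholds nor the hashtag mix accounts for it. Within the hCD2- library, hCD2 was higher in cluster 8 than in clusters 13 and 16 together, at 79.9 CPM and a ratio of 3.20 (2.80 to 3.65). A candidate explanation is the sort itself, with cells of higher hCD2 transcript more likely to fall in the hCD2+ pool. It was found and tested on the same data, and the values are mixed. Within cluster 8 the ratio of hCD2 between the libraries was 1.41 (1.28 to 1.56). Within clusters 13 and 16 the intervals reached 1, at 1.25 (0.994 to 1.56) and 1.14 (0.905 to 1.43). Cluster 8 cells sorted as hCD2- also carried more hCD2 than cells of clusters 13 and 16 sorted as hCD2+. Transcript level alone therefore does not give the pool of a cell. Whether the clusters are separate states or stages was not tested.

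MHC class II genes in ILC3-like cells had a median of -0.75. The free RNA that S100a9 and Cd79a point to predicted a difference of the opposite sign, at most -3.20% of the observed excess of 3800 CPM in the hCD2- library (predicted -122 CPM from S100a9 and -430 CPM from Cd79a), and an upper bound with none in the hCD2+ library was 4.40%. With the same cluster weights in both libraries the median was -0.62, negative in 10 of 10 clusters, and with hashtags weighted equally it was -0.70, negative in 8 of 8. Doublets within a hashtag would bring the other abundant genes of their partners. For B-like, RORgt DC-like, monocyte or macrophage-like, mature DC-like and pDC-like partners together, the rise of these genes over the hCD2+ library accounts for 4.13% of the excess by their median and 9.76% by their upper quartile. With all of their level in the hCD2- library taken as coming from doublets, the bound was 26.6% by the median and 60.9% by the upper quartile, which includes what ILC3-like cells express themselves. Doublets therefore do not account for the whole of it. A difference between ILC3-like cells sorted as hCD2+ and as hCD2- could remain as a hypothesis, found and tested on the same data. The hCD2 transcript hardly separated these cells, at 62.6 and 53.4 CPM.

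Immediate early genes in cluster 8 had a median of 0.85. ILC3-like cells of the same libraries had -0.033, with no member above 0.26, so handling that raised these genes alike in all cells does not account for it. The median was above 0 in alpha-beta T-like cells (0.91, from different clusters in each library), cluster 13 (0.53), B-like cells (0.36, 111 cells in the hCD2+ library) and cluster 16 (0.295). Handling that acts on some cell types more than others therefore stays open. With hashtags weighted equally, over the 4 with at least 10 cells in each library, it was 0.54 and positive in 4 of 4, and among 385 and 97 cells of like depth (25664 to 34012 UMIs) it was 0.66, so hashtag mix and depth may each carry a part of it. With handling open, no biological reading is offered.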
